A study of Mus musculus with 12 samples.

How the data were processed

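Total RNA from 3T3-L1 and 10T1/2 mouse cells was hybridised to 12 Affymetrix arrays as biotin-labelled cRNA, per the labels' protocols. The authors deposited 1 intensity per probe set and array on a linear scale, and the values show that the authors scaled each array so that its trimmed mean, leaving 2% of the probe sets off each end, is 100. The software, the background correction and the detection calls behind these intensities are not given in the sources used here. Both deposited tables hold the same 12 arrays with a largest difference of 0, so 1 of them was used. Log ratio columns that the authors deposited beside the signals were not used. No genome build is given in the sources used here, and so no coordinates are printed.

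The table holds 45101 probe sets, of which 64 controls were left out of every test. Of the remaining 45037, the deposited annotation gave 1 symbol for 38068, several for 1253, none for 5654 and a date in place of a symbol for 62. Only those with 1 symbol were named. Of these, 33189 matched a current RefSeq symbol, 2004 a unique RefSeq synonym and 2875 neither, and the last kept the deposited symbol. A gene was read from the probe set with the highest mean over the 12 arrays, which gave 20670 genes.

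The main values were log2(intensity + 0.8), the pseudocount being the 10th percentile of all intensities, so a fold change understates the change of dim genes. The log2 medians of the arrays differed by up to 0.66, more than the limit of 0.5 set for keeping the deposited scaling, and the arrays were therefore quantile normalised. Genes with a mean under the 40th percentile, a signal of about 7.69, were left out, which left 12402 genes. Signals printed as such are the deposited intensities before this step.

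Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend), with Benjamini-Hochberg adjustment over the 12402 genes and a threshold of 0.05. The 5 arrays transfected with Setdb1 siRNA were compared with the 5 control arrays of the same line, time and experiment label, with the pair as a block. A comparison of 2 arrays with 2 used 3T3-L1 at 0 hr alone, without a block. Interaction terms tested whether the effect differed between the lines or after dexamethasone. The dexamethasone response was tested in 4 pairs of arrays of the same line and siRNA. The Mbd1 and Mcaf1 siRNAs had 1 array each, and the spread came from the other 3T3-L1 arrays at 0 hr, with the experiment as a block and 1 residual degree of freedom, on the assumption that the lone array varies like the others. Single values used exact 2-sided sign-flip permutation tests.

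The experiment letters A and B appear in the labels of the 3T3-L1 arrays and mark shared experiments. Arrays of that line were paired by letter and time. The arrays of the other line carry no letter and were paired by time alone. Experiment A holds 3T3-L1 pairs at both times, and the pairs of the other line may share an experiment too. The pairs are therefore not shown to be independent, although the tests treat them so. Over genes, the difference between experiments A and B in the control arrays correlated with that in the arrays labelled si-Setdb1 (r = 0.427). The labels do not say that arrays of 1 group came from separate cultures beyond these letters, so p-values measure the spread between these arrays, which may be partly technical.

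The comparisons, the 18 gene lists and the rule for naming genes were set before the data were examined. The lists were adipogenic transcription factors, adipocyte lipid and secreted genes, preadipocyte genes and adipogenesis inhibitors, glucocorticoid-induced genes, inflammatory genes lowered by glucocorticoids, germline and early-embryo genes, imprinted genes, clustered protocadherins, interferon-stimulated genes, cell cycle genes, p53 targets, extracellular matrix and myofibroblast genes, bone, cartilage and muscle genes, the H3K9 and DNA methylation machinery, cholesterol synthesis, the unfolded protein and stress response, other cell types, and ribosomal proteins. Each was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests whether the genes of a list move one way and does not set them against other genes. The list medians of lone arrays were ranked among 10000 random lists matched on mean expression. The rule named the targeted genes, Pparg and Cebpa, up to 4 members per list, the 12 largest rises and 12 largest falls of each replicated comparison that passed the threshold in the same direction in every pair, filled up by the smallest p where fewer passed, and 6 per direction for the Mbd1 and Mcaf1 siRNAs. Unnamed probe sets and predicted genes were skipped, and some genes that the rule selects are not named in the text.

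The scripts were tested on simulated data with 12402 genes, 200 of them changed. In the 5-pair comparison 79.9% of changes of 1 on the log2 scale and 96.1% of changes of 2 were recovered, and 5.73% of calls were false. The simulated noise of every comparison had the spread of each gene in the 5-pair fit with its blocks. In the comparison of 2 arrays with 2, recovery was 2% and 75.1%. That comparison has no block, so its real spread includes the difference between experiments, and these rates may be too high. In the dexamethasone comparison it was 68% and 93.9%. For the interactions and for the lone Mbd1 and Mcaf1 arrays it was 0% at both sizes, so a count of 0 there says little.

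Alternatives covered the scaling, the pseudocount, the filter, the treatment of several probe sets per gene, a variance trend, the blocks and leaving out each pair or array. The other deposited table was counted as an alternative too, although it holds the same values and so repeats the main result. A filter at a mean signal of 50 and a pseudocount of 32 were added after the data were seen. So was leaving out pairs in the interactions. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.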

Results

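Gene expression was measured on 12 arrays of RNA from 2 mouse lines. 3T3-L1 cells are preadipocytes, fibroblast-like cells that can turn into fat cells, and 10T1/2 cells are mesenchymal stem cells that can form fat, bone, cartilage or muscle. The cells received a control siRNA (si-Ctr) or siRNAs against Setdb1, Mbd1 or Mcaf1 on day -5 and again on day 0, and were harvested before dexamethasone (0 hr) or after 36 hr (3T3-L1) or 48 hr (10T1/2) in differentiation medium with 0.25 µM dexamethasone, a synthetic glucocorticoid. Setdb1 is a histone methyltransferase that places H3K9 trimethylation. Mbd1 binds methylated DNA, and Mcaf1, now named Atf7ip, is a partner of both. The 12 arrays form 10 groups, and 8 of these hold 1 array. Only si-Ctr and si-Setdb1 in 3T3-L1 at 0 hr have 2 arrays, from experiments A and B. The si-Mbd1 and si-Mcaf1 arrays are 3T3-L1 cells of experiment B. Their titles say 0 hr, although another label says 36 hr, and the titles were followed.

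The 2 replicate arrays correlated over genes with r = 0.967 for si-Ctr and r = 0.964 for si-Setdb1. The 4 arrays of experiment B stood apart from the other 8 in technical signals. Their median signal was 14.9 to 18.1 against 11.2 to 12.2, their Gapdh 3'/5' ratio was 0.691 to 0.747 against 0.859 to 0.933, and their signal for the 5' end of 18S rRNA was 2275 to 3093 against 718 to 1164. On the si-Mbd1 array and the array labelled si-Mcaf1, 12 of the 12 glucocorticoid-induced genes that rose after dexamethasone in the other arrays lay below their lowest level after dexamethasone. Fkbp5, a chaperone that glucocorticoids induce, read 164 on the si-Mbd1 array and 196 on the array labelled si-Mcaf1, against 72.7 to 175.5 at 0 hr and 588 to 2263 after dexamethasone.

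The targeted genes came first, as a check of the labels. The brightest Setdb1 probe set (mean signal 160) was not lower on the arrays labelled si-Setdb1. It read 125 with si-Ctr and 150 with si-Setdb1 in 3T3-L1 at 0 hr in experiment A, 145 and 143 in experiment B, 180 and 155 at 36 hr, 124 and 158 in 10T1/2 at 0 hr, and 121 and 209 at 48 hr. The mean difference was 0.24 (log2, SD 0.37, 5 pairs; exact sign-flip p = 0.188), against a smallest possible p of 0.0625. A dim Setdb1 probe set (mean signal 10.5) was lower in 5 of 5 pairs by a mean log2 difference of -1.57 (SD 0.65; exact sign-flip p = 0.0625, the smallest the 5 pairs allow). It read 24.4 and 9.90 in experiment B (-1.47), and 0.4 to 6.5 in the other 4 pairs, under the filter level. The remaining one (mean signal 12.9) was higher in 5 of 5 pairs by 0.88 (SD 0.54; exact sign-flip p = 0.0625). The brightest Setdb1 probe set therefore goes against the labels, and "the arrays labelled si-Setdb1" is used throughout, directions included.

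Mbd1 read 144 on the si-Mbd1 array against 306 on the si-Ctr array of the same experiment, a log2 difference of -1.15. Its second bright probe set read 62.1 against 132. Atf7ip, the target of the Mcaf1 siRNA, read 155 on the array labelled si-Mcaf1 against 160 on si-Ctr, and 94.8 against 109 with its second bright probe set, so this array also goes against its label and is called the array labelled si-Mcaf1. On that array the brightest Setdb1 probe set read 271, against 145 on si-Ctr. Atf7ip was higher on the arrays labelled si-Setdb1 in 5 of 5 pairs, by 1.66 ± 0.11 (log2, SE; adjusted p = 0.0192). The signals were 187 and 485 in 3T3-L1 at 0 hr in experiment A, 160 and 400 in experiment B, 106 and 403 at 36 hr, 128 and 503 in 10T1/2 at 0 hr, and 106 and 359 at 48 hr. Mbd1 differed by 0.63 in the same comparison and did not pass (adjusted p = 0.171).

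**Figure D1:**
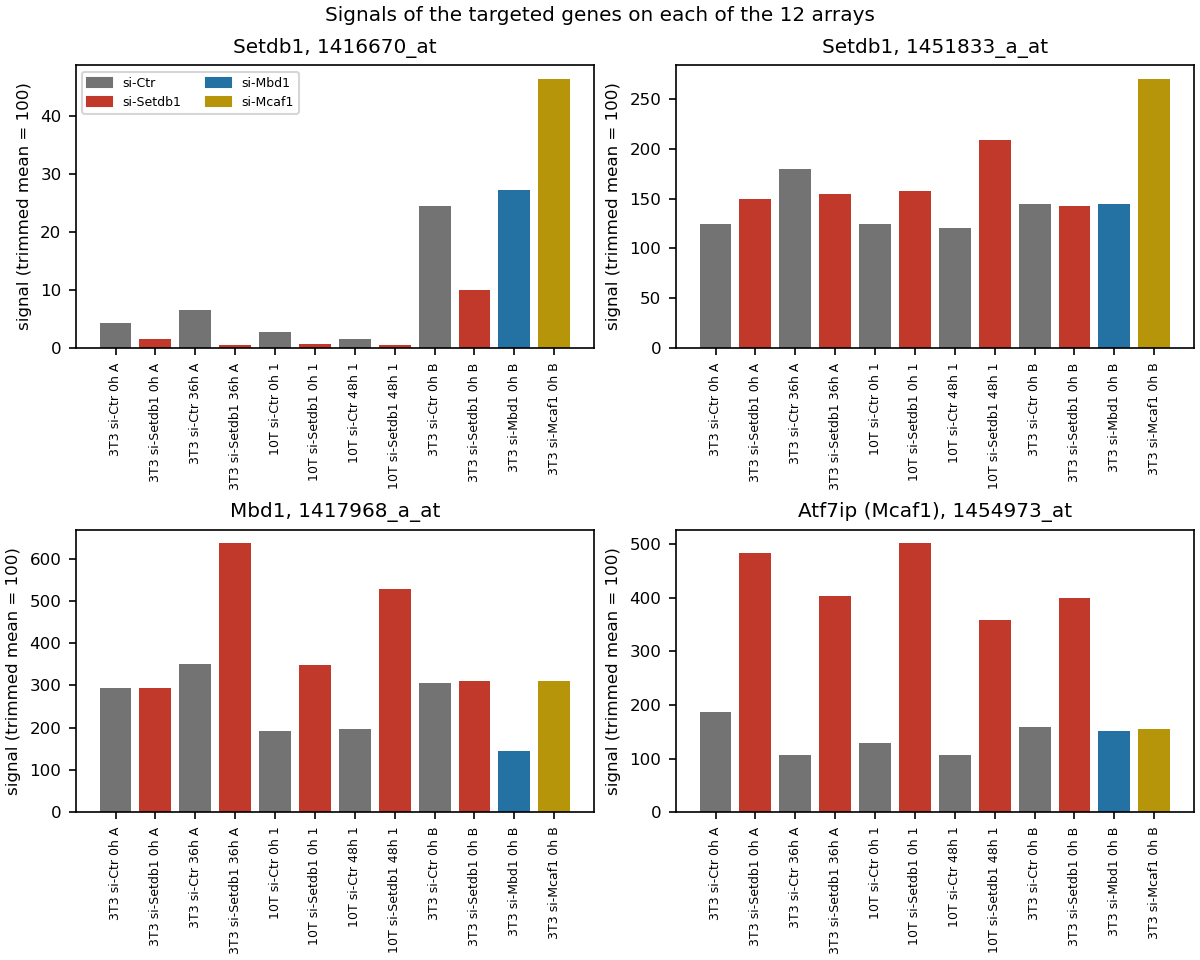
Signals of the targeted genes on each of the 12 arrays (bars; deposited signal, trimmed mean 100), coloured by siRNA. Atf7ip read 106 to 187 on the 5 si-Ctr arrays of the pairs and 359 to 503 on the 5 arrays labelled si-Setdb1, while the brightest Setdb1 probe set read 121 to 180 and 143 to 209.

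The comparison across 5 pairs asked which genes differed between the arrays labelled si-Setdb1 and si-Ctr in both lines and at both times. Genes of fat cells were higher. Cebpa, a transcription factor that drives adipogenesis, was higher in 5 of 5 pairs by 2.43 ± 0.28 (log2, SE; 5.38-fold; adjusted p = 0.0383), with mean signals of 34.5 ± 15.2 and 197 ± 105 (SD, n = 5). Apoe, a lipid carrier that fat cells secrete, rose by 3.19 ± 0.40 (adjusted p = 0.0383; 1.96 to 3.46 over the alternatives), and Slc2a4, the insulin-responsive glucose transporter, rose by 2.19 ± 0.28 (adjusted p = 0.0385; 0.64 to 2.42 over the alternatives, from a mean control signal of 5.14). Pparg, the nuclear receptor at the head of the adipogenic programme, was higher by 1.18 ± 0.19 in 5 of 5 pairs, from 0.36 in 10T1/2 at 0 hr to 1.62 in 3T3-L1 at 36 hr, and narrowly missed the threshold over all genes (adjusted p = 0.0514).

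Of 25 measured adipogenic transcription factors, 2 rose (Cebpa and the oxysterol receptor Nr1h3, 1.07 ± 0.14; 0.47 to 1.15 over the alternatives), 0 fell and 23 did not pass. Adjusted over the list alone, 9 rose, Pparg among them, and 1 fell (Klf4, -0.71). The list was shifted upward (camera adjusted p = 0.00378; adjusted p = 0.325 with an estimated correlation). Of 28 measured adipocyte lipid and secreted genes, 27 had a positive difference, with a median of 1.13. Over all genes 2 rose, and adjusted over the list alone 16 rose. The latter included Adipoq (adiponectin; 5.50 ± 0.88, adjusted p = 0.0510 over all genes) and Fabp4 (a fatty acid carrier; 3.55 ± 0.60, adjusted p = 0.0570). Camera gave an adjusted p of 2.16e-10 for this list (adjusted p = 0.325 with an estimated correlation; fry adjusted p = 0.0342).

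**Figure D2:**
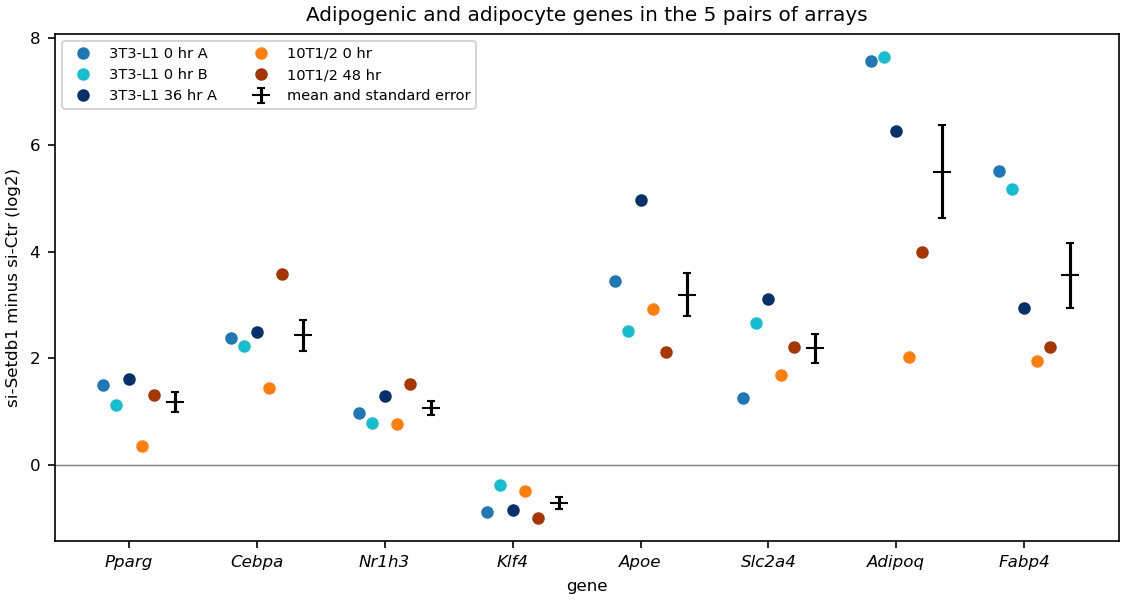
Log2 difference between the array labelled si-Setdb1 and the si-Ctr array of the same pair for 8 adipogenic and adipocyte genes (points, 1 per pair; black bars, mean and standard error). Adipoq differed by 7.57 and 7.65 in 3T3-L1 at 0 hr and by 2.02 in 10T1/2 at 0 hr, and Klf4 lay below 0 in 5 of 5 pairs.

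Other lists moved as well. Of 21 measured p53 targets and cell cycle inhibitors, 18 lay above 0. Gdf15, a stress-induced cytokine (2.16 ± 0.25), Aen, a nuclease (0.64), and Btg2, an antiproliferative factor (0.83), rose, and 8 rose adjusted over the list alone, including the death receptor Fas (0.89). Camera gave an adjusted p of 2.22e-05 (adjusted p = 0.325 with an estimated correlation). All 22 measured cholesterol synthesis genes lay above 0, with a median of 0.31. Mvk, mevalonate kinase, rose by 0.52, and 9 rose adjusted over the list alone, including Dhcr7 (0.54). The list's camera adjusted p was 2.45e-08 (adjusted p = 0.425 with an estimated correlation). Of 13 measured clustered protocadherins, cell adhesion genes of neurons, 2 lay above 0. Pcdhb11 fell by 0.89 and Pcdhb20 fell by 0.54 (-1.01 to -0.25 and -0.60 to -0.29 over the alternatives), and adjusted over the list alone 3 fell, with Pcdhb9 at -1.35. Camera gave an adjusted p of 0.00856 (adjusted p = 0.325 with an estimated correlation).

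Single members passed in lists that did not. In the H3K9 and DNA methylation list (camera adjusted p = 0.125), Atf7ip and Tasor, a subunit of the HUSH silencing complex (0.69), rose, 2 of 31 members, with 2 adjusted over the list alone. In the germline list (0.247) the homeobox gene Rhox5 rose by 1.52 (0.76 to 1.69 over the alternatives), 1 of 5 measured members and 1 adjusted over the list alone. Most genes of that list were not among those tested. In the interferon list (0.0518) Ifit3 fell by 0.82 and Gbp2 fell by 1.11, 2 of 34, with 4 adjusted over the list alone. The call of this list turns with the settings: it passed in 11 of 19 alternatives, with adjusted p from 0.00444 to 0.447 (0.655 with an estimated correlation). The chemokine Cxcl5 fell by 0.98 (-1.06 to -0.65 over the alternatives) in the inflammatory list (0.337; 1 of 13, and 1 adjusted over the list alone), and Hspa1a rose in the stress list (0.364; 1 of 24, with 2 and 2). In the matrix list (0.292) 1 of 34 rose, with 2 higher and 3 lower adjusted over the list alone. No imprinted gene passed over all genes (0 of 22; camera adjusted p = 0.620), although Igf2 was at 2.90 and H19 at 2.15 and adjusted over the list alone 5 were higher and 3 lower. None passed over all genes in the preadipocyte list (camera adjusted p = 0.492; adjusted over the list alone 3 higher and 2 lower), glucocorticoid-induced genes (0.712; 0 and 0), cell cycle genes (0.102; 0 and 0), bone, cartilage and muscle genes (0.822; 0 and 1), markers of other cell types (0.492; 1 and 0) and ribosomal proteins (0.942; 0 and 0).

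Among genes past the threshold, which leaves out Adipoq and Fabp4, and with genes known only by a clone name left out here and below, those that rose most were Wfdc21, a secreted WAP-domain protein (3.42 ± 0.49), Apoe, Actn3, a muscle alpha-actinin (2.98 ± 0.44), Hspa1a, an inducible heat shock protein (2.66 ± 0.23), Apoc1, an apolipoprotein (2.60 ± 0.28), Cebpa, Ltc4s, leukotriene C4 synthase (2.39 ± 0.27), Cables1, a cyclin-dependent kinase adaptor (2.21 ± 0.33), Abhd15 (2.21 ± 0.33), Slc2a4, Gdf15 and P2rx7, an ATP-gated channel (2.03 ± 0.30). Mean control signals of Actn3 (6.64), Hspa1a (7.26), Slc2a4 and P2rx7 (5.56) lay under the filter level, and Wfdc21, Apoe, Ltc4s, Cables1 and Gdf15 read under it on at least 1 control array, so the sizes and order are uncertain. So they are for Abhd15 (0.93 to 2.40 over the alternatives) and Apoc1 (1.62 to 2.83). Among those that fell most were Npc2, a lysosomal cholesterol carrier (-1.76 ± 0.15; signals 4455 and 1311), Zwint, a kinetochore protein (-1.71 ± 0.22; 898 and 271), the collagen Col11a1 (-1.34), Xpnpep2 (-1.30), Fam168b (-1.30), the alcohol dehydrogenase Adh7 (-1.29), Cisd2 (-1.27), the noncoding RNA Tug1 (-1.23 ± 0.08), Pdcd4, a translation inhibitor (-1.23), the vacuolar ATPase subunit Atp6v1d (-1.12) and Tlr4, the lipopolysaccharide receptor (-1.11). Adjusted p was 0.0167 to 0.0476 over these genes, each moving the same way in 5 of 5 pairs. Over the alternatives Zwint ran from -1.88 to -0.35, Xpnpep2 from -1.52 to -0.33 and Tlr4 from -1.19 to -0.59, so the order of the falls is uncertain too. Other probe sets of Zwint and Cisd2 went both ways.

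**Figure D3:**
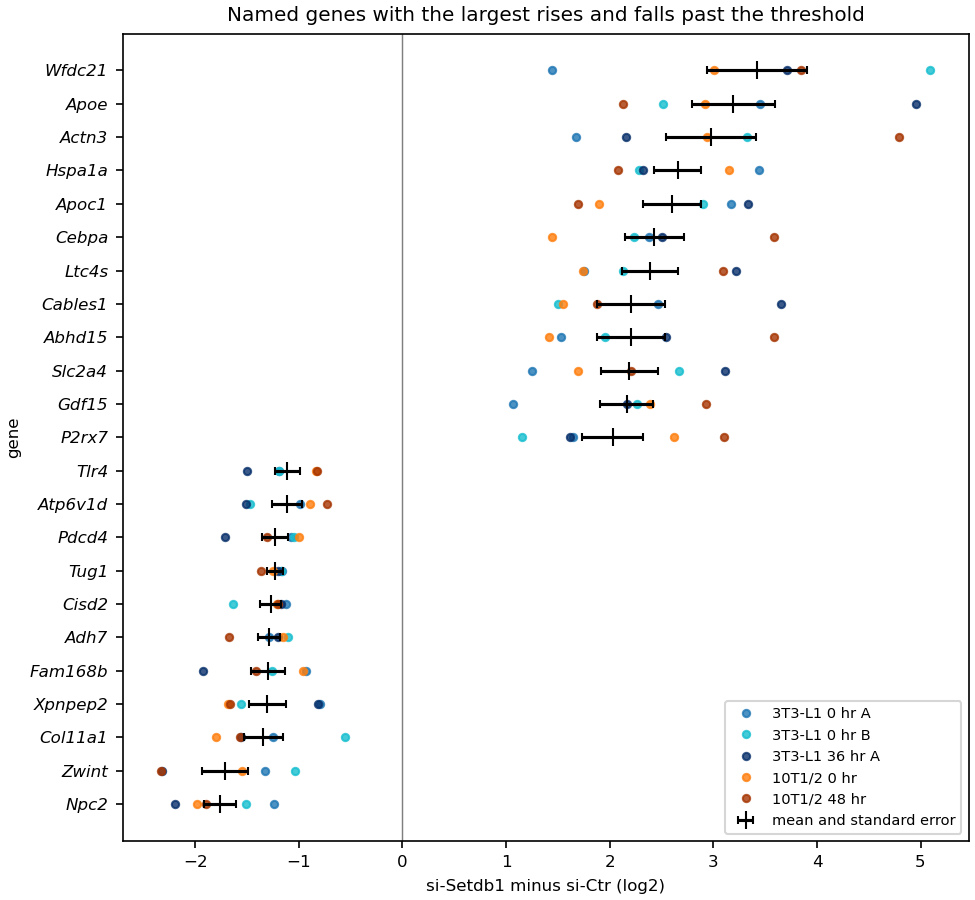
Log2 difference in each of the 5 pairs (coloured points) with the mean and standard error (black) for 12 of the genes that rose most past the threshold and 11 of those that fell most. Tug1 lay between -1.36 and -1.16 in the 5 pairs, and Wfdc21 between 1.44 and 5.09.

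In all, limma called 136 of 12402 genes, 55 higher and 81 lower, and 2761 had an unadjusted p under 0.05, where 620.1 are due by chance. The split was 52 higher and 144 lower with array medians subtracted. Without any 1 of the 5 pairs (3T3-L1 at 0 hr in experiment A, at 0 hr in B or at 36 hr; 10T1/2 at 0 hr or at 48 hr) the count was 0, without the filter it was 0, and with a stricter filter on dim genes it was 843, of which 97 were among the 136.

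In 3T3-L1 before dexamethasone, the only comparison with 2 arrays per group, Adipoq and Fabp4 rose. Adipoq was higher by 7.61 ± 0.20 (adjusted p = 0.00673), a size that rests on control signals of 3.80 and 6.10, under the filter level, and ran from 4.92 to 7.83 over the alternatives. Fabp4 was higher by 5.34 ± 0.22 (adjusted p = 0.0289; 3.68 to 5.49 over the alternatives). With the experiment as a block Adipoq passed (adjusted p = 0.0276) and Fabp4 did not (adjusted p = 0.0862). Cebpa (2.31) and Pparg (1.31) were higher on both arrays and did not pass over all genes (adjusted p = 0.650 and 0.605), but did adjusted over the list alone, where 2 transcription factors rose. Adipocyte genes stood at 27 of 28 above 0 with a median of 0.79, and 12 rose adjusted over the list alone (camera adjusted p = 3.92e-20; adjusted p = 0.283 with an estimated correlation). Interferon-stimulated genes were shifted downward, with 4 of 34 above 0 and a median of -0.51 (camera adjusted p = 5.23e-08; adjusted p = 0.283 with an estimated correlation), although 0 passed singly or adjusted over the list alone. Their lowest p values belonged to Gbp2 (-1.38), Usp18 (-1.02) and Ifi44 (-1.54).

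Further lists passed camera here. Cholesterol synthesis had 21 of 22 genes above 0 (adjusted p = 9.39e-09; adjusted p = 0.302 with an estimated correlation). The transcription factors were up (4.15e-04; 0.302 with an estimated correlation), as were p53 targets, with 16 of 21 above 0 (0.00715; 0.302 with an estimated correlation), and germline genes, with 4 of 5 above 0 and 2, led by Rhox5 at 2.04, adjusted over the list alone (0.0459, passing in 11 of 18 alternatives; adjusted p = 0.352 with an estimated correlation). Clustered protocadherins were down, with 2 of 13 above 0 (0.00715, passing in 13 of 19 alternatives; adjusted p = 0.302 with an estimated correlation).

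Below the 2 genes that passed, the smallest p values belonged to Apoc1 (3.04), Frat2 (3.39), Mrap (3.17), H19 (3.26), Orm1 (2.16), Capns2 (3.13), Hsd11b1, which activates glucocorticoids (2.36), Cd36, a fatty acid transporter (3.89), Wfdc12 (3.49) and Apoe (2.98), at an adjusted p of 0.214. On the lower side were Spata2l (-2.59), Lims2 (-2.60), Ogn (-1.37), Lcn2 (-2.34), Megf10 (-1.52), Efemp1 (-1.23), Nat14 (-1.43), Npc2 (-1.38), Mm2pr (-1.14), Tm9sf1 (-1.13), Tmem64 (-1.12) and Tug1 (-1.16), at adjusted p from 0.214 to 0.652. Many of these sizes moved over the alternatives, with Frat2 from 0.77 to 3.93 and Lcn2 from -3.65 to -0.23. Limma called 2 genes higher and 0 lower, with 674 at an unadjusted p under 0.05, where 620.1 are due by chance. The count was 1 with the experiment as a block, 0 without the si-Ctr array of experiment A or that of experiment B, and 38 (32 higher, 6 lower) with array medians subtracted.

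Whether the difference at the arrays labelled si-Setdb1 depended on the line was tested as an interaction, and 0 genes passed in limma (1161 at an unadjusted p under 0.05). Adipoq differed by -4.16 between 10T1/2 and 3T3-L1 (adjusted p = 0.402), Car3, a carbonic anhydrase, by -4.41, and Lpl, lipoprotein lipase, by 2.29. Over the alternatives Adipoq ran from -5.58 to -2.26, Car3 from -4.93 to -2.29 and Lpl from 1.71 to 2.86. The smallest p values on the higher side in 10T1/2 belonged to Id4, Vegfc, Nnmt, Hcn2, Itpripl2, Slc1a4, Serpina3g, Gas6, Hsf4, Zbtb46, Lrrc75b and Tmc8 (1.38 to 2.63), and on the lower side to Phxr5, Aif1l, Aqp1, Mamdc2, Dcn, Angptl1, Capn6, Ccm2l, Cdhr4, Acan, Lor and Tspan15 (-3.73 to -1.69), at an adjusted p of 0.322 to 0.334. With the mean of the probe sets Zbtb46 reversed (-0.36), so its probe sets disagreed. Over the alternatives Angptl1 ran from -3.58 to -2.41 and Cdhr4 from -4.52 to -0.83. Other probe sets of the genes named here were not read singly for this interaction.

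For the difference with dexamethasone minus without, 0 genes passed in limma as well (989 at an unadjusted p under 0.05). Acsl1 (2.25), Adig (1.81) and Retn, the hormone resistin (4.25), led the adipocyte list, none past the threshold (adjusted p = 0.568, 0.568 and 0.585). The smallest p values belonged to Phxr5, Zfp689, Tmem229a, Fam241a, Gsta4, Hsd17b13, Zfp974, Aco1, Cnnm4, Pomc, Ska1 and Sdk2 on the higher side (1.32 to 3.11) and to Pih1d2, Tmc8, Tmem74, Tmeff2, Syngr1, Frat2, Ankrd1, Mgp, Igfbp5, Kcna7, Slc2a9 and Cxcl16 on the lower side (-2.57 to -1.04), at an adjusted p of 0.442 to 0.568. With the mean of the probe sets Zfp689 (-0.0237) and Slc2a9 (0.0328) reversed, so the probe sets of each disagreed. Other probe sets of the genes named here were not read singly for this interaction.

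Glucocorticoid targets rose after dexamethasone in differentiation medium in 4 of 4 pairs of arrays (both lines, si-Ctr and the arrays labelled si-Setdb1). The treated arrays also differ from those at 0 hr in medium and hours of culture, and no array separates these from dexamethasone. The dexamethasone comparison and the interaction with dexamethasone therefore stand for all of these together. Fkbp5 rose by 3.28 ± 0.15 (log2, SE; 9.69-fold; adjusted p = 0.00629), Per1, a clock gene, by 2.01 ± 0.09, Tsc22d3, the glucocorticoid-induced leucine zipper, by 2.63 ± 0.21, Cebpd, an early adipogenic factor, by 1.44 ± 0.12 and Pdk4, a kinase of fuel choice, by 1.82 ± 0.15. Of 25 measured glucocorticoid-induced genes, 12 rose and 0 fell, and adjusted over the list alone 17 rose and 1 fell. Their median was 1.52 (camera adjusted p = 1.89e-14; adjusted p = 0.0531 with an estimated correlation; fry adjusted p = 1.71e-04).

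**Figure D4:**
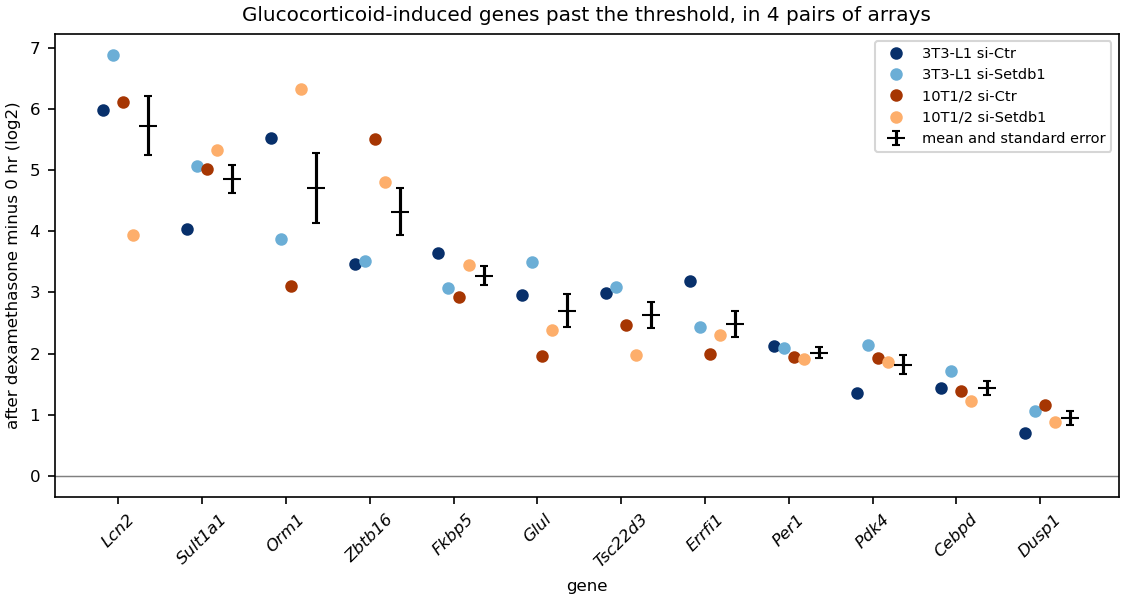
Log2 difference after dexamethasone minus 0 hr in 4 pairs of arrays (coloured points, by line and siRNA) with the mean and standard error (black) for the 12 glucocorticoid-induced genes past the threshold. Each of the 48 points lies above 0, with a mean of 1.44 for Cebpd and of 5.73 for Lcn2.

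Adipocyte genes stood above 0 for 24 of 28 members, where Plin4, a lipid droplet protein (1.40), and Fabp4 (4.16 ± 0.43) rose and 7 rose adjusted over the list alone (camera adjusted p = 5.36e-07; adjusted p = 0.489 with an estimated correlation). The list medians were 0.17 (si-Ctr) and 0.94 (labelled si-Setdb1) in 3T3-L1, and 0.38 and 2.20 in 10T1/2. The shift was thus larger on the arrays labelled si-Setdb1 in both lines. Adipoq was at 2.51 and did not pass over all genes (adjusted p = 0.114). Of the adipogenic transcription factors, Cebpd and Nr1h3 (1.75; 0.73 to 1.97 over the alternatives) rose, and 7 rose and 2 fell adjusted over the list alone. That list did not pass (camera adjusted p = 0.0873), and Pparg was at 1.06 (adjusted p = 0.0806). Acta2 (-0.99), Tagln and Myl9, contractile genes of myofibroblasts, fell, 3 of 34 in the matrix list, with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.193).

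Several lists passed camera downward with 0 members past the threshold over all genes, and not all in both lines. Cell cycle genes were lower in 10T1/2, with list medians of -1.23 (si-Ctr) and -1.13 (labelled si-Setdb1), but stood at -0.12 and 0.18 in 3T3-L1. Over the 4 pairs their median was -0.53, with Mcm5 at -0.92 and Cdc6 at -0.88, and 0 adjusted over the list alone (camera adjusted p = 2.75e-06; adjusted p = 0.597 with an estimated correlation). Inflammatory genes had 1 of 13 above 0 and 4 lower adjusted over the list alone, with Mmp9 at -2.28, Ptgs2 at -1.64 and Cxcl5 at -2.53 (0.00129; adjusted p = 0.469 with an estimated correlation). Over the alternatives Mmp9 ran from -2.54 to -0.996, Ptgs2 from -1.98 to -0.895 and Cxcl5 from -2.96 to -1.48. Preadipocyte genes had 5 of 25 above 0, with Gata3 at -1.37 and list medians of -0.55 and -0.52 in 3T3-L1 and 0.05 and -0.39 in 10T1/2, and adjusted over the list alone 1 higher and 8 lower (0.00229; adjusted p = 0.567 with an estimated correlation). Protocadherins had 0 of 13 above 0, with Pcdhb22 at -1.35 and 5 lower adjusted over the list alone (3.98e-05; adjusted p = 0.449 with an estimated correlation). Gata3 ran from -1.57 to -0.41 over the alternatives, and Pcdhb22 from -1.49 to -0.56. Interferon-stimulated genes were lower in 3T3-L1, with list medians of -1.01 (si-Ctr) and -0.82 (labelled si-Setdb1), and stood at 0.18 and 0.10 in 10T1/2. Over the 4 pairs Ifit2 was at -0.93, with 1 lower adjusted over the list alone (0.00620, passing in 14 of 18 alternatives; adjusted p = 0.702 with an estimated correlation). The H3K9 list had 9 of 31 above 0, with Hells at -0.81 and 0 adjusted over the list alone (0.0164, passing in 15 of 18 alternatives; adjusted p = 0.449 with an estimated correlation).

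The largest rises past the threshold were in Lcn2, lipocalin 2 (5.73 ± 0.49; 2.63 to 6.52 over the alternatives), the aldehyde dehydrogenases Aldh1a7 (5.38) and Aldh1a1 (4.74), the sulfotransferase Sult1a1 (4.86 ± 0.23), the acute phase gene Orm1 (4.71), Ctla2a (4.41), the transcription factor Zbtb16 (4.32 ± 0.39), Fabp4, Ifi207 (4.03), the dipeptidase Dpep1 (3.76), Fkbp5 and Clca1 (3.10 ± 0.09). At 0 hr Lcn2, Aldh1a1, Orm1, Ctla2a, Zbtb16 and Ifi207 read under the filter level on at least 1 array, so their sizes and order are uncertain. The largest falls past it were in the prostaglandin receptor Ptger4 (-2.21), the growth factor Igf1 (-2.19 ± 0.09; 703 to 3366 at 0 hr and 148 to 710 after), Tagln (-2.11), Sertad4 (-2.05), Efnb2 (-2.02), Hs6st2 (-1.78), Lmcd1 (-1.74), Myl9 (-1.66), Gas2 (-1.64), Runx1 (-1.53), Etv5 (-1.47) and Phlda1 (-1.47). Their order is uncertain too: over the alternatives Lmcd1 ran from -2.04 to -0.44, Runx1 from -1.66 to -0.63, Gas2 from -1.74 to -0.74, Etv5 from -1.59 to -0.71, Efnb2 from -2.13 to -1.12, Ptger4 from -2.51 to -1.23 and Tagln from -2.37 to -1.40, and Clca1 among the rises from 1.69 to 3.20. Adjusted p over these 24 was 0.00379 to 0.0493, and 1 other probe set each of Efnb2 and Runx1 went the other way. Limma called 95 genes, 62 higher and 33 lower (2588 at an unadjusted p under 0.05). The count was 0 without the filter, 462 with a stricter one (58 shared), and 1, 4, 14 and 12 without the si-Ctr or si-Setdb1 pair of 3T3-L1 or the si-Ctr or si-Setdb1 pair of 10T1/2. Of the 136 and 95 genes called in the 2 replicated comparisons, 3 rose in both, Nr1h3 among them, where 0.275 are due for independent lists. Against these, 1 gene, Zhx3, was lower at the label si-Setdb1 and higher after dexamethasone, where 0.405 are due. The lists are not independent, as the comparisons share 8 arrays.

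The si-Mbd1 array and the array labelled si-Mcaf1 were compared with si-Ctr, to ask how far their differences resembled those of the arrays labelled si-Setdb1. With 1 array each there was no replicate of the siRNA, and 0 genes passed in limma for either (666 and 905 at an unadjusted p under 0.05). On the array labelled si-Mcaf1, Rhox5, a germline homeobox gene, had the smallest p on the higher side (4.85 ± 0.23, adjusted p = 0.339; signals 756 against 34.5 on si-Ctr of experiment B, 113 on the array labelled si-Setdb1 and 39.8 on si-Mbd1). Usp17la (3.40), Wfdc12 (2.70), Pcdh17 (2.81), Itga9 (2.32) and Slc7a2 (2.32) were the others selected by p. Over the alternatives Wfdc12 ran from 1.24 to 2.80, Pcdh17 from 1.09 to 3.01, Itga9 from 0.35 to 2.83 and Slc7a2 from 1.11 to 2.38. On the lower side E2f2 (-3.51), Ifit1 (-3.21), Oasl2 (-2.54), Zbp1 (-2.86), Rtp4 (-2.53) and Ifi44 (-2.93) had the smallest p (over the alternatives E2f2 ran from -3.85 to -0.43 and Zbp1 from -3.12 to -0.81), and of these all but E2f2 are interferon-stimulated.

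The interferon list had a median of -1.43 on the array labelled si-Mcaf1, and 29 of 34 members were lower adjusted over the list alone against 0 over all genes (camera adjusted p = 7.23e-31; adjusted p = 0.863 with an estimated correlation; fry adjusted p = 0.162). Against the si-Ctr array of experiment B alone its median of -1.53 lay at percentile 0 of 10000 random lists matched on expression. On the si-Mbd1 array the same list had a median of 0.43 (camera adjusted p = 2.18e-08; adjusted p = 0.755 with an estimated correlation), with Usp18 at 1.29 and Rtp4 at 0.88. Cholesterol synthesis genes were higher by a median of 0.41 on the array labelled si-Mcaf1 and of 0.28 on the si-Mbd1 array, and stress response genes by 0.14 on the latter. These lists passed camera at the preset correlation and not with an estimated one. Against the si-Ctr array of experiment B alone, cholesterol genes stood at 0.31 (labelled si-Setdb1), 0.20 (si-Mbd1) and 0.28 (labelled si-Mcaf1). Stress response genes stood at 0.15, 0.17 and 0.11 in this order. These arrays share that control, so a low control array cannot be told apart from a change on the si-Mbd1 array or the array labelled si-Mcaf1.

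**Figure D5:**
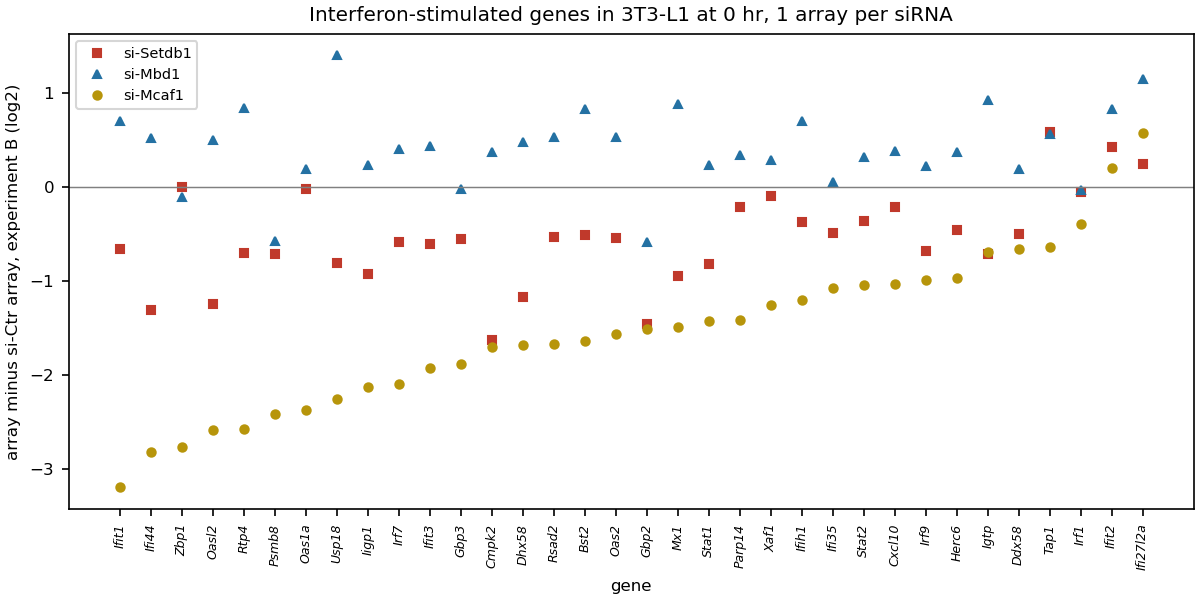
Log2 difference from the si-Ctr array of experiment B for 34 interferon-stimulated genes in 3T3-L1 at 0 hr, 1 array per siRNA (squares, labelled si-Setdb1; triangles, si-Mbd1; circles, labelled si-Mcaf1). The circles lie below 0 for 32 of 34 genes.

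On the si-Mbd1 array, Sfrp1, a secreted Wnt antagonist (2.97), Hoxa9 (3.01), Clmn (2.26), Pcdh17 (2.23), Akr1c12 (1.97) and Trpv2 (2.23) had the smallest p values on the higher side, and Wnt5b (-2.90), Tmem143 (-2.93), Cd55 (-2.20), Pcdhb19 (-2.06), Stxbp2 (-2.10) and Fgf9 (-1.94) on the lower, at an adjusted p of 0.622. Most were dim: Sfrp1 read 16.9 against 1.80 on si-Ctr. Its other probe sets were not read singly on the si-Mbd1 array. Over the alternatives Sfrp1 ran from -0.17 to 3.56 and Wnt5b from -4.29 to -0.32. Cebpa was at 0.96 (0.56 to 1.33 over the alternatives) and Adipoq at 1.73 (0.42 to 1.94) on the si-Mbd1 array, and neither passed. Against the si-Ctr array of experiment B alone, the adipocyte list had a median of 0.31 on the si-Mbd1 array (percentile 100 of the random lists). On the array labelled si-Mcaf1 it was 0.11 (percentile 96.3). The adipogenic transcription factors stood at -0.01 and 0.06 (percentiles 45.4 and 83.5). Both arrays share that single control.

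The genes that rose most with the label si-Setdb1 were read on the si-Mbd1 array and on the array labelled si-Mcaf1, in this order. They were chosen in a comparison that includes experiment B and its control, so a control value by chance low raises the differences of all 3 siRNAs, and their signs are no test of a shared change. Hspa1a was at 2.13 and 2.23 and Cebpa at 0.96 and 0.77, Apoc1 at 0.24 and 2.18, Actn3 at 1.14 and 3.16, Wfdc21 at -0.01 and 1.74, Apoe at -0.07 and 1.64, Ltc4s at 0.91 and 0.93, Cables1 at 1.09 and 1.97, Abhd15 at 0.15 and 0.09, Slc2a4 at 0.86 and -0.25, Gdf15 at 1.58 and 0.75, and P2rx7 at -2.29 and 2.43. Of those that fell, Xpnpep2 was at -0.61 and -0.89, Pdcd4 at -0.30 and -0.56, Zwint at -0.19 and -0.55, Tug1 at -0.02 and -0.29, Fam168b at -0.09 and -0.19, Npc2 at 0.04 and -0.06, Col11a1 at 0.37 and -0.06, Adh7 at -0.28 and 0.17, Cisd2 at -0.20 and 0.12, Atp6v1d at 0.22 and -0.25, and Tlr4 at 0.51 and 0.17. None of these genes passed on either array.

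Over all genes, and with genes not independent replicates, the difference of the si-Mbd1 array from the control of experiment B correlated with the mean difference of the 4 pairs labelled si-Setdb1 outside that experiment with r = 0.064, that of the array labelled si-Mcaf1 with r = 0.122 and that of the array labelled si-Setdb1 with r = 0.369. Against the pair of experiment A at 0 hr alone, matched for line and time, r was 0.0357, 0.0519 and 0.327 in this order, with the sign shared by 49.2%, 47.6% and 62.5% of genes. Among the 200 genes with the smallest p in those 4 pairs, the sign was shared by 54.5% for the si-Mbd1 array, 60% for the array labelled si-Mcaf1 and 92.5% for the array labelled si-Setdb1. Within experiment B, where the arrays share 1 control, the correlations were 0.401 (si-Mbd1 with the label si-Setdb1), 0.428 (the label si-Mcaf1 with the label si-Setdb1) and 0.485 (si-Mbd1 with the label si-Mcaf1), all below the 0.50 simulated for unchanged groups with a shared control. Changes particular to 1 siRNA lower the correlation and the share of like signs, so values below the simulated ones are no test of shared changes. The sign was shared by 61.8%, 59.2% and 65.6% of genes, against a simulated 66.7%. The covariances were 0.0969, 0.116 and 0.0999 against a simulated 0.0924, and part of any excess may come from the single control.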

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

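The tests of the scaling over the mean of the 3 pairs and of the array splits were written down before their results, and the other tests named here were chosen only after the result was seen.

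The effect at the label si-Setdb1 differed between the lines in 6 gene lists, by the interaction list test with the preset correlation. Germline genes differed by a median of -0.92 (10T1/2 minus 3T3-L1; 0 of 5 above 0, camera adjusted p = 5.35e-04), but with no filter the direction reversed and the list did not pass (adjusted p = 0.587). Brdt stood at -1.33 (-1.50 to -0.33 over the alternatives) and Rhox5 at -0.92. Most genes of this list were not among those tested, so the 5 do not stand for the whole list. Outside experiment B, Brdt read 18.4 to 30 in 3T3-L1 and 4.5 to 14.9 in 10T1/2, and Rhox5 15 to 76.7 and 5.6 to 12.8. In 10T1/2 both thus came near or under the filter level. Bone, cartilage and muscle genes differed by -0.64 (2 of 12 above 0; 9.74e-04), cholesterol synthesis genes by -0.31 (2 of 22; 9.74e-04) and cell cycle genes by -0.30 (5 of 35; 8.23e-05). Interferon-stimulated genes differed by 0.22 (24 of 34; 9.74e-04), with Ifi44 at 1.76 (0.74 to 1.89 over the alternatives), and p53 targets by 0.29 (16 of 21; 0.0203). Some members read near or under the filter level of 7.69 in 1 line, which leaves little room for a fall there. Outside experiment B, Oasl2 read 0.5 to 6.5 and Zbp1 0.6 to 8.2 in 10T1/2, though Bst2 read 88.9 to 120.3. The bone gene Dlx5 read 0.3 to 4.1 in 3T3-L1, though Runx2 read 140.8 to 351.2. With dexamethasone minus without, adipocyte genes differed by 0.78 (24 of 28; 1.46e-05) and cell cycle genes by 0.27 (26 of 35; 3.61e-04). The 8 calls held in 14 to 17 alternatives of 18 or 19, counting the other deposited table, which repeats the main values. None of the 8 passed with an estimated correlation, where adjusted p was 0.553 to 0.578 between the lines and 0.821 for dexamethasone, and 0 genes passed singly in limma (1161 and 989 at an unadjusted p under 0.05). The labels give the 10T1/2 arrays no experiment, and the hours of treatment differ between the lines.

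Adipocyte genes were higher on the arrays labelled si-Setdb1 before dexamethasone, with list medians of 0.63 and 1.08 in the 2 pairs of 3T3-L1 and 0.20 in 10T1/2. Dexamethasone-treated cells under a 0 hr label would have raised the glucocorticoid list, whose highest median in these pairs was 0.14. In 3T3-L1 both pairs lie within an experiment, so a difference between experiments cannot enter them, and their medians are no separate test of it. Under the other scalings the median was at least 0.63 in each pair (0.56 for the mean of the 3 pairs), so the choice among these scalings does not account for the rise. The rise recurred in both experiments, but each pair holds a single array per siRNA, and other differences between the arrays of a pair were not tested. In 10T1/2 the median was at least 0.20 under the other scalings, with 17 of 28 members above 0 in the main one. There p53 targets (0.41) and adipogenic transcription factors (0.22) stood higher, and the preadipocyte and inflammatory lists stood at 0.19 and 0.18. Scaling or another difference between the 2 arrays therefore cannot be told apart from a change.

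The brightest Setdb1 probe set was not lower on the arrays labelled si-Setdb1, while Atf7ip was higher by 1.66. Labels exchanged in some pairs would make their differences correlate below 0 over genes, and the lowest correlation between pairs was 0.15, which does not rule out an exchange in all 5. The brightest probe set may read transcripts that the siRNA left in place: a dim Setdb1 probe set was lower by a mean of -1.57, and its only pair above the filter level, that of experiment B, was lower too (24.4 and 9.90; -1.47). The other 4 pairs of that probe set lay near the floor of the signal, and 1 pair does not decide. Another dim Setdb1 probe set went the other way, higher by a mean of 0.88 and reading 11.7 and 22 in experiment B. The explanation therefore cannot be told apart. Protein levels were not given in the sources used here.

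Interferon-stimulated genes were lower on the array labelled si-Mcaf1, where Ifit1 read 33.6 against 248 on si-Ctr. A high control array is not enough to account for it, since the smallest median gap to the other 4 3T3-L1 arrays at 0 hr was -0.67. A shift of all genes of like signal is not either, as the list lay at percentile 0 of 10000 random lists. Off-target effects of the siRNA sequence and differences between cultures could produce the same fall, and with 1 array neither was tested.

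Other splits of the arrays were counted. For the label si-Setdb1, 1 of 100 splits, the real one, called as many genes as the 136, and the highest other count was 0. For dexamethasone it was 1 of 32, against 95 genes and a highest other count of 0. Most of these splits part fewer pairs than the real one and so hold less information. Exchanging arrays within pairs gives only 16 and 8 splits, of which 1 and 1 called as many genes, too few for a share under 0.05.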

How the results depend on the processing

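The alternatives were set before the data were examined, except a filter at a mean signal of 50, a pseudocount of 32 and the leaving out of pairs in the interactions, which were chosen only after the result was seen. Over 210 gene results and 3149 alternative values, 99.8% kept the direction, with 464 weaker, 209 stronger and 6 reversed. Most of these genes were chosen by their change or p on the same arrays. The other deposited table, counted among the alternatives, repeats the main values, so the share overstates the stability. Over 48 list results and 872 values, 85 were weaker, 21 stronger and 16 reversed. Except where said, the cause was not tested.

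The number of genes past the threshold at the label si-Setdb1 was the least stable result. Against 136 in 5 pairs it was 88 with no pseudocount, 234 with 4 times the pseudocount and 823 with a pseudocount of 32 (126 of the 136 shared). It was 0 with no filter, 843 with the stricter filter and 800 with a mean signal above 50. The mean of the probe sets gave 2, all probe sets 8, and a variance trend 880 (129 shared). It was 115 with the deposited scaling and 196 with array medians subtracted. Leaving out 1 pair gave 0 to 0. Both the filter and a larger pseudocount by construction remove noise of dim genes, from which the moderated variance is partly borrowed.

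In the comparison of 2 arrays with 2, against 2 genes, there was 1 with the deposited scaling, 38 with array medians subtracted, 0 with no filter, 1 with the mean of the probe sets, 0 with all probe sets, 4 with a variance trend, 5 with a pseudocount of 32, 1 with the 6 arrays in 1 model and 0 to 2 with 1 array left out. With the experiment as a replicate block it was 1, where Fabp4 had an adjusted p of 0.0862.

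After dexamethasone, against 95 genes, there were 150 with 4 times the pseudocount, 499 with a pseudocount of 32, 0 with no filter, 462 with the stricter filter, 393 with a mean signal above 50, 19 with the mean of the probe sets, 27 with all probe sets and 574 with a variance trend. Leaving out 1 pair gave 1 to 14.

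Where 0 genes passed, the interaction with the line gave 8 with the stricter filter, 34 with a variance trend, 8 with a mean signal above 50 and 57 with a pseudocount of 32. The interaction with dexamethasone gave 2 with a variance trend and 5 with a pseudocount of 32. The si-Mbd1 array gave 46 with the stricter filter, 112 with a variance trend, 14 with a mean signal above 50 and 36 with a pseudocount of 32. The array labelled si-Mcaf1 gave 250, 352, 107 and 246 in the same order. Without the experiment as a replicate block both stayed at 0.

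With an estimated correlation the number of lists past the threshold was 0 in each of the 7 comparisons, from 5 (label si-Setdb1, 5 pairs), 7 (3T3-L1 at 0 hr), 6 (line), 2 (interaction with dexamethasone), 8 (dexamethasone), 3 (si-Mbd1) and 2 (labelled si-Mcaf1). The adjusted p became 0.325 for adipogenic transcription factors, 0.325 for adipocyte genes, 0.0531 for glucocorticoid-induced genes and 0.863 for interferon-stimulated genes on the array labelled si-Mcaf1. Fry gave 0.162 for the last, and 0 lists in 3T3-L1 at 0 hr, 0 in either interaction, 0 for si-Mbd1, 0 for the label si-Mcaf1 and 2 for dexamethasone.

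Other settings also moved the list counts. The mean of the probe sets gave 9 in 5 pairs and 5 for si-Mbd1, and no filter gave 4 in 3T3-L1 at 0 hr. The deposited scaling gave 4 in the interaction with dexamethasone and 7 for si-Mbd1, and array medians subtracted gave 4 and 7. For si-Mbd1 the stricter filter gave 6 and a variance trend 7. For the label si-Mcaf1 the stricter filter gave 4, a variance trend 5 and a pseudocount of 32 gave 4. With 1 pair or array left out there were 5 to 7 lists in 5 pairs, 5 to 7 in 3T3-L1 at 0 hr, 3 to 9 for the line, 2 to 3 for the interaction with dexamethasone and 7 to 8 for dexamethasone. Over these settings the adjusted p of adipocyte genes in 5 pairs ran from 3.34e-14 to 2.03e-08, of transcription factors from 0.00148 to 0.0129 and of glucocorticoid-induced genes after dexamethasone from 4.49e-15 to 3.04e-12.

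Directions reversed for lists that stood near 0 in 5 pairs. Ribosomal proteins reversed with the deposited scaling (adjusted p = 0.189), array medians subtracted (0.36), the mean of the probe sets (0.903) and without the 3T3-L1 pair of experiment B (0.864), the range with 1 pair left out being 0.747 to 0.967. Bone, cartilage and muscle genes did with array medians subtracted (0.922), the stricter filter (0.287), the mean of the probe sets (0.838), a mean signal above 50 (0.734) and without the 10T1/2 pair at 0 hr (0.906) or at 48 hr (0.747), the range being 0.482 to 0.906. Glucocorticoid-induced genes did with no filter (0.954), the mean of the probe sets (0.970) and without the 3T3-L1 pair at 36 hr (0.915), the range being 0.585 to 0.915. With the mean of the probe sets so did inflammatory genes (0.501) and imprinted genes (0.970). In the interaction with the line, germline genes reversed with no filter (0.587).

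Among named genes, the mean of the probe sets reversed Setdb1 in 5 pairs (-0.15), Zbtb46 in the interaction with the line (-0.36), Zfp689 (-0.0237) and Slc2a9 (0.0328) in that with dexamethasone, and Atf7ip on the array labelled si-Mcaf1 (0.25). For these the probe sets of a gene disagreed. A pseudocount of 32 reversed Sfrp1 on the si-Mbd1 array (-0.17).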

Other observations

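The comparison of the lines and the genes named in it were chosen only after the result was seen, while the splits were written down before. Among the genes that differed between the lines, Il1rn, an interleukin 1 antagonist, was higher in 10T1/2 by 8.42 ± 0.41 (log2, SE), the enkephalin precursor Penk by 7.64 ± 0.71, the imprinted adaptor Grb10 by 7.58 ± 0.24 (signals 6.00 to 15.1 in 3T3-L1 and 2287 to 2597 in 10T1/2), and the cartilage collagen Col2a1 by 6.46 ± 0.56. In 3T3-L1, Hoxd8 was higher (-6.97 ± 0.25), as were Igf2bp3 (-6.44 ± 0.17), the preadipocyte marker Dlk1 (-6.11 ± 0.17; 2725 to 5108 and 25.5 to 98.4) and the cell cycle inhibitor locus Cdkn2a (-5.63 ± 0.22; 1916 to 2998 and 31 to 57.1). Il1rn (0.7 to 6.2), Penk (1 to 10.6), Grb10 and Col2a1 (8.4 to 12.4) in 3T3-L1, and Hoxd8 (1.9 to 4.9) and Igf2bp3 (5.5 to 9.6) in 10T1/2, read near or under the filter level on the lower side, so the sizes of these differences are uncertain.

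Of the lists, interferon-stimulated genes were lower in 10T1/2 by a median of 0.72 (camera adjusted p = 0.00814; adjusted p = 0.781 with an estimated correlation). Of these, 10 of 34 passed the threshold, near the share over all genes (3584 of 12402), and all 10 were lower. Some of the 10 read under the filter level in 10T1/2, such as Oasl2 (0.5 to 6.5) and Cxcl10 (0.6 to 7.4), while Bst2 read 88.9 to 120.3. Bone, cartilage and muscle genes went both ways, 5 higher and 2 lower of 12 (camera adjusted p = 0.206), as did imprinted genes, 6 higher and 6 lower. Limma called 3584 genes over the 8 arrays outside experiment B, 1758 higher and 1826 lower in 10T1/2 (5289 at an unadjusted p under 0.05). The block was siRNA and treatment, so 36 hr in 3T3-L1 stood against 48 hr in 10T1/2. All 3T3-L1 arrays here are of experiment A, so the p-values do not cover the spread between experiments of that line. Of 32 splits, 1, the real one, called as many, and the highest other count was 0, but only 8 part all pairs, too few for a share under 0.05. The labels give the 10T1/2 arrays no experiment.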
